A study of Sus scrofa with 21 samples.

How the data were processed

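RNA was measured in uterine endometrium of Large White sows on 21 1-colour Agilent porcine arrays, in 7 groups of 3 arrays each. Per the labels, 9 pregnant sows were killed on day 13, 18 or 24 after insemination, 3 sows a day, and each gave endometrium from a site where a conceptus was attached and from the stretch between attachment sites (the inter-site). The control group consisted of 3 sows that received inactivated sperm and were sampled on day 13. Total RNA was extracted with Trizol, and 0.5 µg was amplified and labelled with Cy3 by an Agilent low-input kit, per the labels' protocols. The groups are called non-pregnant, and attachment site or inter-site of day 13, 18 or 24, and arrays are named by group and replicate number. Per the labels, the p-values rest on 3 sows per group, but the arrays of a group were not shown to be independent. The labels do not say which libraries share a sow, so the comparisons of sites were fitted without pairing, and libraries of 1 group that matched at on-off probes were not shown to come from different sows.

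The deposited scanner files hold spot intensity from Agilent Feature Extraction, version 10.7.3.1 per the file headers and 10.7 per the submitters' processing notes. Per the file headers, the processed intensity of each spot was background-subtracted and detrended within its array by that software, and no step between arrays was recorded. Other columns used were the software's 0 or 1 flags for signal well above background, saturation and outlier spots, per the file headers, and the median spot and background intensity as deposited. The authors' table of processed values was on the log2 scale and had been quantile normalized without centring of probes: each column had a median of 5.85, and 19 of the 21 columns correlated best with the scanner values of their own sample. The columns of replicates 2 and 3 of the day 24 inter-sites followed each other's scanner files. The software behind that table is not given in the sources used here, and it served only as an alternative; the scanner files decided which replicate number an array carries.

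Each array held 45220 spots, of which 43803 were not controls. Control spots and spots with an outlier flag were left out, and log2 values of the 50 probes printed 5 times were averaged, which left 43603 probes. No spot was saturated. The log2 processed signal minus the array's 75th percentile was the value analysed, so all levels are log2 values relative to that percentile. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which kept 30091 probes and left out 13512. Between 62.3% and 77.1% of probes were well above background on an array, the 75th percentile of the processed signal lay between 354 and 854, and the median signal was 2.34 to 3.88 times the median background. The number of arrays limits the precision.

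Gene names came from the RefSeq accession of a probe, matched without version to a table of pig RefSeq genes. Of 5779 probes with such an accession, 5461 matched 1 symbol, 318 matched none and 0 matched several, which named 2389 genes. The other probes, 38142 without a symbol in all and 7535 of them designed on Ensembl transcripts, were tested and counted but not named. Where a gene had several probes, the one with the highest mean over the 21 arrays stood for it, and 2013 genes entered the list tests in this way.

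All 21 arrays were fitted with 7 group means in limma 3.58.1 (lmFit and eBayes, 14 residual and 2.71 prior degrees of freedom) under R 4.3.3. Probes were counted as changed at an adjusted p under 0.05 (Benjamini-Hochberg within each comparison). The 9 comparisons were pregnancy at each site type on day 13, attachment against inter-site on each day, and day 18 against 13 and day 24 against 18 at each site type; 2 further contrasts asked whether the site difference changed between days. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over all 189 tests of 21 lists in 9 comparisons. The alternatives for this test were camera with an estimated correlation and fry. Where a probe was not well above background on any array of 1 group, a bound is given as at least N-fold: the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest value among probes well above background.

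The 25 lists were the interferon response, MHC and antigen presentation, histotroph and secreted uterine proteins, prostaglandin synthesis and receptors, steroid receptors and steroid metabolism, adhesion molecules and mucins, nutrient transporters, calcium and ion handling, angiogenesis and vasoactive signals, extracellular matrix and remodelling, the cell cycle, cytokines and chemokines, growth factor, WNT and homeobox factors, complement and coagulation, immediate early and heat shock genes, and markers of conceptus and trophoblast, epithelium, ciliated epithelium, stromal fibroblasts, smooth muscle, endothelium, T and NK lymphocytes, macrophages and other myeloid cells, B and plasma cells, and blood cells and platelets. A list with under 5 measured members was not tested, which left out ciliated epithelium (1 measured member), stromal fibroblasts (3), B and plasma cells (0) and blood cells (4). The groups, tests, lists, naming rule and alternatives chosen beforehand were fixed before the data were examined.

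Named genes followed this rule: in each comparison, among changed probes with 1 symbol, well above background on all 3 arrays of both groups and with no overlap between the 3 and 3 arrays, the 8 with the largest rise and the 8 with the largest fall; the 3 brightest per direction of those given as bounds; up to 4 members of each list described, by smallest adjusted p with changed members first; and any of 16 genes with textbook roles in the pig uterus past the threshold (among them SPP1, S100G, STC1, FGF7, IL1RAP, LPAR3, PTGES, PTGS2, AKR1B1, HPGD, ESR1, PGR, ACP5, RBP4 and MUC4). FGF7, IL1RAP, HPGD and MUC4 had no named probe. Of the 2 contrasts of site by day, up to 5 genes per direction were to be named.

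Alternatives chosen before the data were examined were quantile normalization, subtraction of the array median, normexp background correction with an offset of 50, no filter, a filter on all 21 arrays, the authors' table, a fit of only the groups compared, the replicate number as a block, slide as a block, eBayes with trend and robust settings, array weights, an added 2-fold threshold, genes in place of probes, other list tests, and leaving out each array in turn. Chosen after seeing the data were normexp on the median rather than the mean spot signal, slide as a random block, slide as a block for lists and named genes, fits without pairs of libraries that stood apart, and a block of libraries that shared on-off probes, that is, probes that were either bright or dim. For these, group explained under 0.5 of the variation in state, and the absolute correlation with the smooth muscle list was under 0.5. The arrays lay on 6 slides and were scanned on 2 days; the second day held 1 array, so scan day was not a usable block. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots, and statmod 1.5.0 estimated block correlations.

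The fit was tested on simulated data for pregnancy at attachment sites, with 200 of 30026 probes changed. With 3 arrays per group it recovered 25.4% of probes changed 2-fold, 67.2% of those changed 4-fold and 92.4% of those changed 8-fold, with 6 false calls. The list test, run on 2013 genes with the interferon list shifted by 1 log2 unit, called that list in 3 of 3 comparisons and 0 of 180 other list tests. In both runs the simulated probes and arrays varied independently of each other. They therefore do not show how many false calls the fit makes when libraries are related, or the list test when genes vary together.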

Results

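Gene expression was measured in the endometrium of pregnant sows at conceptus attachment sites and at the inter-sites between them on days 13, 18 and 24, and in non-pregnant sows on day 13, with 3 arrays in each of 7 groups. The question, from the series title, is which genes differ in the uterine lining during implantation in the pig. Each array measured 43603 probes, of which 62.3% to 77.1% were well above background, and 30091 were tested. Levels are log2 signal relative to the array's 75th percentile, and differences are log2 fold changes with their standard error (SE).

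More probes were called at attachment sites than at inter-sites, but counts do not test a difference between site types. The tests of a change in the site difference called 0 and 3 probes. Without day 13 inter-site replicate 1, pregnancy at inter-sites called 612. From day 13 to day 18 at attachment sites, the lists of the interferon response, antigen presentation and T and NK lymphocytes rose (8 of 25, 12 of 22 and 2 of 14 members called). From day 18 to day 24 these lists fell there (7, 5 and 2 members called) while 1157 probes rose. With an estimated correlation these list tests gave adjusted p = 0.478 to 0.634. Relabellings of the arrays gave a p as small in 6, 4 and 13 of 100 for the rises. For the falls they did so in 12, 7 and 5 of 100. Limma called 536 probes for pregnancy at attachment sites on day 13 and 136 at inter-sites, against 0 for attachment site over inter-site on days 13 and 18 (2441 and 1411 at an unadjusted p under 0.05) and 84 on day 24. With slide as a block, or without non-pregnant replicate 1, both pregnancy counts were 0. They were also 0 with libraries that shared on-off probes as a random block (estimated correlation 0.335). With slide as a random block (estimated correlation -0.056) both stayed within 1.5 times. The list results rest on a test with a small fixed correlation between genes: 42 lists passed it over the 9 comparisons, 0 of these with an estimated correlation, and 33 of 100 relabellings of the arrays gave as many.

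**Figure D1:**
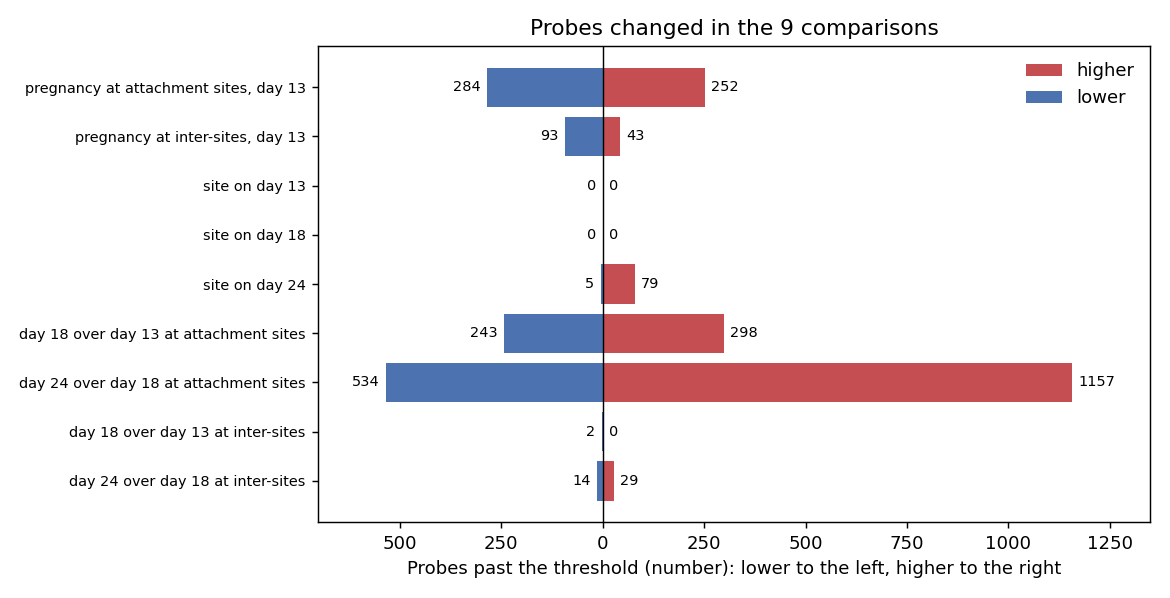
Number of probes changed in each of the 9 comparisons (limma, 3 arrays per group), with lower probes to the left and higher probes to the right. The longest pair of bars is day 24 over day 18 at attachment sites, with 1157 higher and 534 lower probes.

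Some libraries stood apart from their group. DKK1, a secreted WNT inhibitor, had levels of -4.62, -5.37 and -4.62 on the non-pregnant arrays and of 3.54 to 5.68 on 16 of the 18 arrays of pregnant sows, but of -3.23 on replicate 1 of the day 13 inter-sites and -6.13 on replicate 3 of the day 24 inter-sites. The same libraries had FST levels of -2.25 and -3.16, in the range of the non-pregnant arrays (-3.48 to -2.05), and PGR levels of 2.16 and 3.04. Across probes, which are not independent replicates, replicate 3 of the day 24 inter-sites correlated at 0.988 with non-pregnant replicate 3 and at 0.942 with both other libraries of its group. Replicate 1 of the day 13 inter-sites correlated at 0.970 and 0.968 with these 2 libraries, and at 0.943 and 0.934 with its own group. On-off probes were chosen so that group explained under 0.5 of the variation in their state, so matches within a group may partly reflect it. At 45 such probes, non-pregnant replicate 3 and day 24 inter-site replicate 3 matched at 93.3%. That non-pregnant library matched each other library of its group at 37.8%. Replicates 1 and 2 also matched within the non-pregnant group (91.1%), at attachment sites of days 13, 18 and 24 (93.3%, 86.7% and 86.7%) and at day 18 inter-sites (91.1%). Attachment-site and inter-site libraries of the same day matched as closely, up to 95.6% (day 13 attachment-site replicate 1 and inter-site replicate 2), and 16 of the 18 libraries of pregnant sows had their best match on the same day. The libraries fell into 9 sets by these matches, 4 of which held replicates of 1 group. The estimated correlation within a set was 0.335, so a group may hold fewer than 3 independent samples. Transcripts of smooth muscle (7 measured members, among them ACTA2, DES and CNN1) varied within groups: the list's median per array, relative to the mean of all arrays, ranged from -1.93 to 3.52, and non-pregnant replicates 1, 2 and 3 had 2.89, 2.73 and -1.93.

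The first comparison asked what pregnancy changes at attachment sites on day 13, when pig conceptuses elongate. FST (follistatin, which binds activin) rose 32.2-fold (log2 fold change 5.01, SE 1.03, adjusted p = 0.0291, n = 3 arrays per group). DKK1 rose by 9.82 log2 units (SE 2.28, adjusted p = 0.0405), from a level that was above background on 2 of 3 non-pregnant arrays. PGR, the progesterone receptor, fell from 3.28 ± 0.23 to 1.19 ± 0.06 (SD, n = 3, adjusted p = 0.0166). Among the largest rises were KMO of tryptophan breakdown (3.28), lipoprotein lipase LPL (3.18), PHGDH of serine synthesis (2.65) and PDK4, which restrains pyruvate use (2.55), together with SAA3 (4.07), CTGF (3.37) and KLF5 (3.02). The largest falls were those of the protease inhibitor SLPI (-3.91), the nuclear receptor NR4A3 (-3.26), SGCD of the sarcoglycan complex of muscle (-2.95), the mucin MUC20 (-2.86), CALCB (-2.76), the GTPase RND3 (-2.66), and the proliferation genes MYC (-2.28) and CCND2 (-2.16).

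Of genes below background in 1 of the groups, OPTC, a matrix proteoglycan, was at least 84.8-fold higher at attachment sites, SCNN1A, a subunit of the epithelial sodium channel, at least 3.27-fold higher, and the kinase STK26 at least 2.27-fold lower. The growth factor, WNT and homeobox list rose (23 members measured, 3 called higher over all probes, 4 adjusted over the list alone, median 0.31, adjusted p = 0.0250, or adjusted p = 0.478 with an estimated correlation). Its called members were DKK1, KLF5 and EGF (2.43), and IGF1R had 1.35. Its median was 0.33 with slide as a block, and 0.25 and 0.17 within slides 1 and 3. Epithelial markers rose (0 of 8 called over all probes, 1 adjusted over the list alone, median 0.73, adjusted p = 0.00783, or adjusted p = 0.634 with an estimated correlation), and the tight-junction gene CLDN3 had 1.79. The median was 0.74 with slide as a block and 1.38 and 0.29 within the slides. The cell cycle list fell (0 of 11 called, also adjusted over the list alone, median -1.77, adjusted p = 0.0207, or adjusted p = 0.779 with an estimated correlation). CDC20 was at -2.71 (above background on 2 of 3 attachment-site arrays), TOP2A at -2.65 and CDK1 at -2.37. Non-pregnant replicate 3 had a list median of 2.74, against -0.48 and 0.10 on the other non-pregnant arrays; without it the call ended (adjusted p = 0.293), as it did without attachment-site replicate 2 (adjusted p = 0.0562). The median was -1.91 with slide as a block, and -1.0 and -3.17 within slides. The median of the smooth muscle list was -1.70, -4.54 within slide 1 and 0.71 within slide 3, and the list was not called (adjusted p = 0.314).

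Limma called 536 probes, 252 higher and 284 lower, 64 named genes among them, and 100% of these probes differed in the same direction within slides 1 and 3, against 78.9% and 73.2% of all probes; choosing probes by their pooled difference nearly fixes the 100%. With slide as a block 0 probes were called (5098 at an unadjusted p under 0.05, against 6090 without the block), and without non-pregnant replicate 1 or 2 0 and 1 remained past the threshold, without attachment-site replicates 1, 2 and 3 48, 12 and 44. Normexp background correction called 26 probes, 18 higher and 8 lower, and a block of libraries that shared on-off probes called 0.

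At inter-sites on day 13, PGR also fell relative to non-pregnant sows, by 1.77 log2 units (SE 0.36, adjusted p = 0.0424, n = 3 per group). HTR2A, a serotonin receptor, fell by 3.29 (SE 0.56, adjusted p = 0.0255) and RND3 by 2.04. Smaller falls were found for PPP1R14B, an inhibitor of protein phosphatase 1 (-1.55), the tropomyosin TPM4 (-1.38), the valyl-tRNA synthetase VARS (-1.30), the RNA-binding protein HNRNPAB (-1.26) and RANBP1 of nuclear transport (-1.19). ANPEP, a membrane peptidase, rose 4.37-fold (log2 fold change 2.13, SE 0.43, adjusted p = 0.0408). DKK1 had 7.0 (SE 2.28, adjusted p = 0.141), with the level of -3.23 on replicate 1 given above.

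The angiogenesis and vasoactive list rose (0 of 22 called over all probes, 1 adjusted over the list alone, median 0.37, adjusted p = 0.0207, or adjusted p = 0.646 with an estimated correlation). NOS2, an inducible nitric oxide synthase, was at 1.15, ANGPT2 at 0.63, RAMP1 at -0.65 and HIF1A at -0.75. The median was 0.34 with slide as a block, and 0.43 and 0.24 within slides 3 and 6. The growth factor, WNT and homeobox list rose (0 of 23 called, also adjusted over the list alone, median 0.21, adjusted p = 0.0179, or adjusted p = 0.478 with an estimated correlation). KLF5 was at 2.51 (levels of -0.74, 2.21 and 1.69 on inter-site replicates 1, 2 and 3), EGF at 1.58 and IGF2 at -0.64. The median was 0.18 with slide as a block, and 0.44 and 0.05 within slides. Smooth muscle markers fell (0 of 7 called, also adjusted over the list alone, median -2.94, adjusted p = 0.0409, or adjusted p = 0.784 with an estimated correlation). CNN1 was at -3.25 and ACTA2 at -3.11. With slide as a block their median was -2.37 (adjusted p = 0.0839), and within slides 3 and 6 it was 0.30 and -4.91. Leaving out 1 library ended the call of the smooth muscle list (non-pregnant replicates 1 and 2, inter-site replicates 1 and 3: adjusted p = 0.224, 0.223, 0.120 and 0.0562), of angiogenesis (non-pregnant replicate 3, inter-site replicates 1 and 2: 0.0883, 0.0718 and 0.0788) and of the growth factor list (inter-site replicate 2: 0.0573).

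Limma called 136 probes, 43 higher and 93 lower, with 20 named genes, and 0 with slide as a block (3365 at an unadjusted p under 0.05, against 5302 without it); within slides 3 and 6, 100% of them and 76.5% and 72.4% of all probes went the same way. The count was 0 without non-pregnant replicate 1 or 2 or inter-site replicate 2 or 3, 317 without non-pregnant replicate 3, 612 without inter-site replicate 1, and 1162 without both libraries that had low DKK1. The block of libraries sharing on-off probes and normexp each called 0.

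The comparisons at attachment sites and inter-sites shared 98 called probes, all in the same direction, 30 higher and 68 lower; PGR and RND3 were among the shared genes. Independent lists would share 0.360 and 0.878 probes. Simulated unchanged groups that shared 3 simulated control arrays had 0 called probes in common, a count nearly fixed, since no probe was changed there. The simulation held no structure among libraries, so it does not show how many shared calls the real controls produce. The log2 fold changes correlated across probes at 0.784 (0.499 in the simulation), with a covariance of 0.459 (0.122 in the simulation). Part of the excess may come from the shared controls, since 3 arrays cannot be split into groups that each keep a pair. Without non-pregnant replicate 1 or 2, or inter-site replicate 2 or 3, 0 probes were shared, without non-pregnant replicate 3 226, without attachment-site replicates 1, 2 and 3 23, 10 and 17, and without inter-site replicate 1 480. With the block of libraries sharing on-off probes, limma called 0 probes in both comparisons.

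Attachment site and inter-site were next compared within a day, to ask what differs where a conceptus lies. On day 13 epithelial markers were higher at attachment sites (0 of 8 called, also adjusted over the list alone, median 0.48, adjusted p = 0.0268, or adjusted p = 0.763 with an estimated correlation). CLDN3 was at 1.08 and CLDN7 at 0.78. Their median was 0.76 with slide as a block and 0.21 within slide 3. The cytokine and chemokine list was lower (0 of 41 called, also adjusted over the list alone, median -0.17, adjusted p = 0.0321, or adjusted p = 0.779 with an estimated correlation). IL1B was at -0.89, CXCL2 at -0.64, TNF at -0.38 and FST at 1.55, the last with -2.25 on inter-site replicate 1 and 2.25 and 2.22 on the other inter-site arrays. The median was -0.22 with slide as a block and -0.06 within slide 3. Leaving out 1 library ended the call of epithelium (attachment-site replicate 1, inter-site replicate 1: adjusted p = 0.0526 and 0.256) and of cytokines (attachment-site replicate 2, inter-site replicates 1 and 2: 0.126, 0.143 and 0.0732). The smooth muscle median was 1.28 (not called, adjusted p = 0.222). Another scaling moved the median of all probes in this comparison by up to 0.107 log2 units from -0.07, and normexp moved it to -0.29. Limma called 0 probes (lowest adjusted p = 0.0899, 2441 at an unadjusted p under 0.05, and 1627 with slide as a block, which also called 0).

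On day 18 genes of antigen presentation were higher at attachment sites than at inter-sites as a list (0 of 22 called, also adjusted over the list alone, median 0.88, adjusted p = 1.82e-09, or adjusted p = 0.503 with an estimated correlation). The immunoproteasome subunits PSMB9 were at 1.42 and PSMB10 at 1.22 and the class II gene SLA-DQA1 at 1.07. T and NK lymphocyte markers were higher (0 of 14 called, also adjusted over the list alone, median 0.78, adjusted p = 0.0246, or adjusted p = 0.779 with an estimated correlation). CD2 was at 1.17 and CD3D at 1.15. The cell cycle list was higher (0 of 11 called, also adjusted over the list alone, median 1.04, adjusted p = 0.0256, or adjusted p = 0.779 with an estimated correlation). CDC20 was at 2.18 (above background on 1 of 3 inter-site arrays) and CDK1 at 2.12. Epithelial markers were lower (0 of 8 called, also adjusted over the list alone, median -0.44, adjusted p = 0.0274, or adjusted p = 0.767 with an estimated correlation). CLDN7 was at -0.57 and EPCAM at -0.54. The growth factor, WNT and homeobox list was lower (0 of 23 called, also adjusted over the list alone, median -0.25, adjusted p = 0.0308, or adjusted p = 0.478 with an estimated correlation). KLF5 was at -1.34, MET at -1.04 and AREG at 1.79 (above background on 2 of 3 inter-site arrays). With slide as a block the medians were 0.65 for antigen presentation, 0.32 for lymphocytes (adjusted p = 0.343), -0.05 for the cell cycle (adjusted p = 0.482), -0.63 for epithelium and -0.07 for the growth factor list (adjusted p = 0.267); no slide held both groups. For antigen presentation, 13 of 100 relabellings of the arrays, the real one included, gave a p as small. Antigen presentation stayed called without any 1 library. The others did not: lymphocytes had an adjusted p of 0.718 and 0.0920 without attachment-site replicates 1 and 3 and of 0.112 and 0.0521 without inter-site replicates 1 and 2, and the cell cycle 0.0724 and 0.118 without attachment-site replicates 1 and 3 and 0.0835 without inter-site replicate 2. Epithelium had an adjusted p of 0.0600 and 0.450 without attachment-site replicates 1 and 2 and 0.111 without inter-site replicate 1, and the growth factor list 0.172 and 0.0895 without attachment-site replicates 2 and 3 and 0.0804 and 0.116 without inter-site replicates 1 and 2. Limma called 0 probes (lowest adjusted p = 0.0683, 1411 at an unadjusted p under 0.05), also with slide as a block (918), and 3 without attachment-site replicate 1. The block of libraries sharing on-off probes called 2. The smooth muscle median was 1.10 (not called, adjusted p = 0.432), and 2.90 with slide as a block (adjusted p = 0.00210).

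On day 24 the cytokine IL6 was 28.1-fold higher at attachment sites than at inter-sites (log2 fold change 4.81, SE 0.62, adjusted p = 0.00257, n = 3 per group). PGLYRP1, which binds bacterial cell walls, was higher by 5.96 (SE 1.15, adjusted p = 0.0371), the water channel AQP8 by 4.36, and PNPLA3 of lipid droplets by 4.25. Within slides 2 and 4 the differences were 6.4 and 3.7 for IL6 and 8.6 and 3.9 for PGLYRP1. For AQP8 they were 7.8 and 4.0, and for PNPLA3 6.8 and 2.6. The inter-site array on slide 2 was replicate 3, which resembled a non-pregnant library. GRN (progranulin, 2.19), CBR1 (carbonyl reductase, which converts prostaglandin E2 to F2 alpha, 2.06) and STARD4 of cholesterol transport (1.95) were higher as well. CYP19A3, a pig aromatase that makes oestrogen, was at least 8.37-fold higher. Of the 84 probes called, 79 were higher and 5 lower, 19 named genes were among the higher, and 0 of the 5 lower probes carried a symbol.

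Prostaglandin genes were higher at day 24 attachment sites (1 of 13 called over all probes, 5 adjusted over the list alone, median 0.74, adjusted p = 0.00430, or adjusted p = 0.478 with an estimated correlation); beside CBR1, the reductases AKR1C1 and AKR1B1 had 6.70 (adjusted p = 0.0743) and 2.48 (adjusted p = 0.0870). AKR1C1 was above background on 2 of 3 inter-site arrays (levels -0.30, 1.36 and -5.82), and without inter-site replicate 3, which resembled a non-pregnant library, its difference was 4.58. Their median was 0.94 with slide as a block, and 1.45 and 0.65 within slides 2 and 4. Conceptus and trophoblast markers were higher (0 of 20 called over all probes, 8 adjusted over the list alone, median 0.52, adjusted p = 0.000112, or adjusted p = 0.483 with an estimated correlation). Embryonic globin HBE1 was at 7.24, alpha-fetoprotein AFP at 6.59, the steroid enzyme CYP17A1 at 3.03 and GATA3 at 2.48, none past the threshold over all probes. The aromatase measured in this list was CYP19A1 (0.05). The called CYP19A3, another name written for that member, did not enter the list. AFP and CYP17A1 were above background on 2 of 3 inter-site arrays, and without inter-site replicate 3 HBE1 had 5.73 and AFP 5.14. The median was 0.48 with slide as a block, and 1.33 and 0.68 within slides. Complement and coagulation genes were higher (0 of 26 called, also adjusted over the list alone, median 0.51, adjusted p = 0.0101, or adjusted p = 0.478 with an estimated correlation). PLG was at 4.01 (above background on 1 of 3 inter-site arrays) and C6 at 1.79. The median was 0.44 with slide as a block, and 0.63 and 0.29 within slides. Histotroph genes, which encode uterine secretions, were higher (0 of 27 called, also adjusted over the list alone, median 0.74, adjusted p = 0.0226, or adjusted p = 0.478 with an estimated correlation). IGFBP3 was at 2.07, SPP1 at 2.05, CST3 at 1.74 and CTSB at 0.91. The median was 0.69 with slide as a block, and 1.19 and 0.36 within slides. Leaving out inter-site replicate 3 ended the calls of histotroph (adjusted p = 0.0891) and complement genes (0.0532), the latter also without attachment-site replicate 1 (0.0898). The smooth muscle median was -0.33, 0.67 within slide 2 and -2.97 within slide 4 (not called, adjusted p = 0.464).

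With slide as a block limma called 22 probes, and within slides 2 and 4 100% of the 84 and 78.7% and 67.1% of all probes went the same way. Without attachment-site replicates 1, 2 and 3 the count was 170, 12 and 14, without inter-site replicates 2 and 3 309 and 19, and without both low-DKK1 libraries 18; without inter-site replicate 1 it was 44. The block of libraries sharing on-off probes called 245. The 3 day-specific site differences were not shown to differ by their counts: the test of a change in the site difference called 0 probes between days 13 and 18 (2380 at an unadjusted p under 0.05; 0 called and 1668 with slide as a block; 1 called without day 18 attachment-site replicate 1) and 3 between days 18 and 24 (966; 0 called and 818 with slide as a block; 7 called with the block of libraries sharing on-off probes). Of these 3, 2 belonged to CYP19A3 (adjusted p = 0.0233, above background in 1 of the 4 groups, so that no fold of the change is given) and IL6 (3.86, SE 0.56, adjusted p = 0.0314, with site effects of 0.45 on day 18, where it was above background on 2 of 3 arrays of each group, and 4.30 on day 24, from another IL6 probe than the one above), and the other carried no symbol; this probe of IL6 and the unnamed probe were chosen after their values were seen. Another scaling moved the median of all probes in the first of these tests by 0.122.

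**Figure D2:**
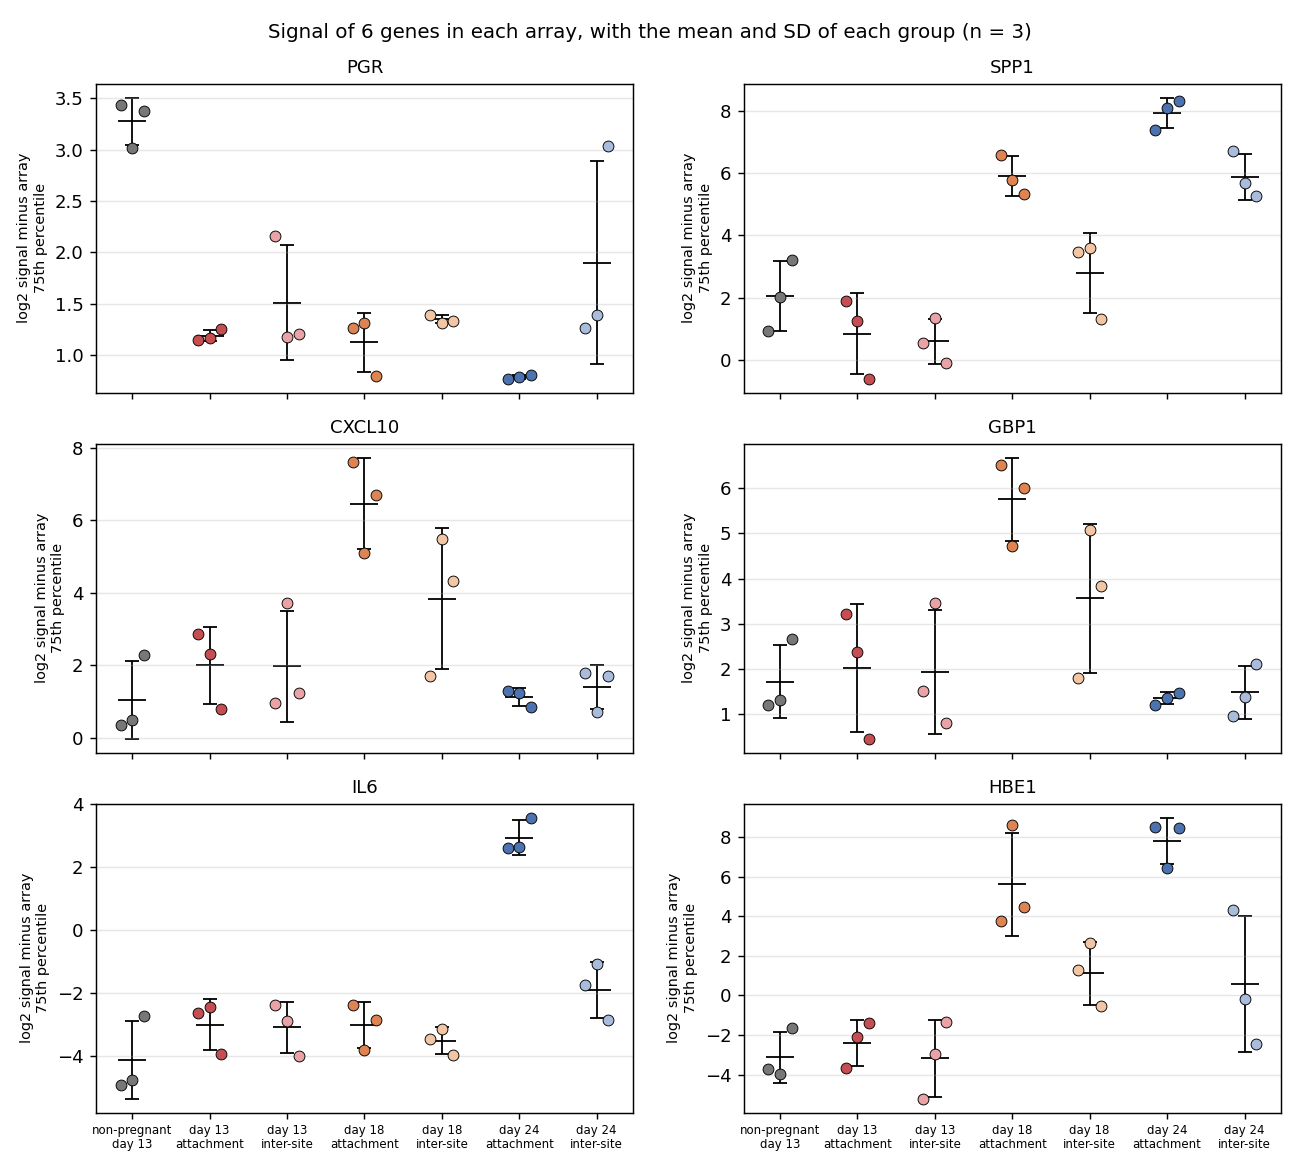
Level of PGR, SPP1, CXCL10, GBP1, IL6 and HBE1 on each array (log2 signal minus the array's 75th percentile), with the mean and SD of each group (n = 3). PGR was 3.28 ± 0.23 in non-pregnant sows and 1.19 ± 0.06 at day 13 attachment sites, with 1 day 24 inter-site array at 3.04; CXCL10 and GBP1 were highest at day 18 attachment sites (6.47 ± 1.27 and 5.75 ± 0.92).

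Between day 13 and day 18, chemokines and interferon-induced genes rose at attachment sites: CXCL9 by 4.83, CXCL10 by 4.47 (SE 0.92, adjusted p = 0.0287, n = 3 per group), CCL2 by 3.14 and the guanylate-binding protein GBP1 by 3.73 log2 units. SPP1 (osteopontin, a ligand of integrins at the conceptus-maternal interface) rose 33.1-fold, from 0.85 ± 1.29 to 5.90 ± 0.64 (SD, n = 3, adjusted p = 0.00984). Embryonic globin HBE1 rose 255-fold (log2 fold change 8.0, SE 1.54, adjusted p = 0.0237), SLPI by 4.10 and lysozyme LYZ by 3.37. HBE1 levels on day 18 replicates 1, 2 and 3 were 3.75, 8.61 and 4.47. The conceptus and trophoblast list was not called here, and whether RNA from conceptus tissue in the pieces contributed was not tested. CXCL11 was at least 19.4-fold higher and STK26 at least 3.52-fold higher on day 18, and BHMT, a methyltransferase of methionine synthesis, at least 3.62-fold lower. Falls were smaller: the mucosal chemokine CCL28 (-3.05), PHGDH (-2.74), EPHX1 (-1.65), AHCYL1 (-1.63), CYP39A1 (-1.46), SAT1 of polyamine breakdown (-1.40) and KLHDC3 (-1.07).

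The interferon response list rose (8 of 25 called over all probes, 22 adjusted over the list alone, median 1.47, adjusted p = 3.5e-13, or adjusted p = 0.478 with an estimated correlation). GBP2 was at 2.85 beside the genes named. The median was 1.88 with slide as a block and 2.63 within slide 3. Antigen presentation genes rose (12 of 22 called over all probes, 19 adjusted over the list alone, median 1.91, adjusted p = 8.48e-16, or adjusted p = 0.478 with an estimated correlation), among them PSMB9 (2.71), the class I gene SLA-3 (2.30) and the class II genes SLA-DQA1 (2.20) and SLA-DRA (2.18). The median was 1.91 with slide as a block and 2.73 within slide 3. T and NK lymphocyte markers rose (2 of 14 called over all probes, 10 adjusted over the list alone, median 1.51, adjusted p = 0.000181, or adjusted p = 0.507 with an estimated correlation), namely CD2 (2.79) and CD3D (2.04, above background on 2 of 3 arrays on day 13). The median was 1.47 with slide as a block and 2.31 within slide 3. Macrophage and myeloid markers were not called as a list. Their medians on replicates 1, 2 and 3 were 0.05, -0.58 and -0.75 on day 13 and 1.29, 0.50 and 0.615 on day 18. In the cytokine list 3 of 41 members rose and 1 fell over all probes, and 13 and 1 adjusted over the list alone (median 0.63, adjusted p = 0.000363, or adjusted p = 0.507 with an estimated correlation), with CCL2 and CCL8 (2.66) among those that rose and CCL28 the 1 that fell. Its median was 0.55 with slide as a block and 1.09 within slide 3.

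Complement and coagulation genes rose as well (3 of 26 called over all probes, 5 adjusted over the list alone, median 0.47, adjusted p = 0.0411, or adjusted p = 0.483 with an estimated correlation), namely C2 (2.71), C1S (1.44) and the C1 inhibitor SERPING1 (1.35). The median was 0.51 with slide as a block and 0.59 within slide 3. Epithelial markers fell as a list (0 of 8 called over all probes, 4 adjusted over the list alone, median -0.91, adjusted p = 0.00718, or adjusted p = 0.634 with an estimated correlation). KRT8 was at -1.50, CLDN7 at -1.28 and CLDN3 at -1.17. The median was -0.96 with slide as a block and -0.68 within slide 3. The complement call ended without day 13 replicates 2 and 3 (adjusted p = 0.0553 and 0.0511) and day 18 replicates 1 and 3 (0.128 and 0.0528), and the epithelium call without day 18 replicate 2 (0.0696). Smooth muscle markers had a median of 1.69 (not called, adjusted p = 0.269), and of 2.64 with slide as a block (adjusted p = 0.0365).

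Limma called 541 probes, 298 higher and 243 lower, with 72 named genes, and 12 with slide as a block; within slide 3, 100% of them and 80.2% of all probes went the same way. Normexp called 111, 81 higher and 30 lower, and the block of libraries sharing on-off probes 24. Leaving out day 13 replicates 1, 2 and 3 left 170, 10 and 43 probes, leaving out day 18 replicates 1 and 2 left 9 and 169, and without day 18 replicate 3 there were 3728.

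From day 18 to day 24 at attachment sites, IL6 rose 60.4-fold (log2 fold change 5.92, SE 0.62, adjusted p = 0.000185, n = 3 per group). The secreted peptide OSTN (osteocrin) rose 712-fold (9.48, SE 2.24, adjusted p = 0.0229), CRISP3 by 7.46, the aldo-keto reductase AKR1C1 by 6.49, the protease inhibitors SERPINA1 and SERPINA3-2 by 6.11 and 5.86, the pregnancy-associated glycoprotein PPAG3, a product of trophoblast, by 5.51 and DPPA5 by 5.30. OSTN levels on day 18 replicates 1, 2 and 3 were -1.16, -0.85 and -4.07. Whether RNA from conceptus tissue in the pieces contributed to these rises was not tested. Of the prostaglandin enzymes, AKR1B1 rose by 3.31 and PTGES by 2.0. BPI, an antibacterial protein, was at least 99.8-fold higher on day 24, plasminogen PLG at least 15-fold higher and the glucose transporter SLC2A2 at least 9.2-fold higher. The largest falls were those of interferon-induced genes: CXCL10 by 5.35 (SE 0.92, adjusted p = 0.00526), CXCL9 by 4.74, GBP1 by 4.40, GBP2 by 3.98, UBD by 3.35, IRF1 by 2.35 and PSMB9 by 2.20, with CD180 by 2.41; CXCL11 was at least 14.3-fold lower and SNCAIP at least 1.45-fold lower, though its log2 fold change was 0.45 with normexp.

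The interferon response list fell (7 of 25 called lower and 1 higher over all probes, 10 and 1 adjusted over the list alone, median -0.69, adjusted p = 1.29e-07, or adjusted p = 0.634 with an estimated correlation); the member that rose was SOCS3, an inhibitor of cytokine signalling (1.91, chosen after its value was seen). Its median was -0.67 with slide as a block and -0.39 within slide 2. Antigen presentation genes fell (5 of 22 called over all probes, 18 adjusted over the list alone, median -1.19, adjusted p = 2.83e-12, or adjusted p = 0.478 with an estimated correlation), namely PSMB9, the peptide transporter TAP1 (-1.97), PSMB10 (-1.63), SLA-8 (-1.10) and PSME1 (-0.95, chosen after its value was seen). The median was -1.03 with slide as a block and -0.84 within slide 2. T and NK lymphocyte markers fell (2 of 14 called over all probes, 9 adjusted over the list alone, median -1.29, adjusted p = 2.63e-07, or adjusted p = 0.478 with an estimated correlation), namely the granzymes GZMA (-2.07, but 0.0206 with normexp, and above background on 2 of 3 arrays on day 24) and GZMB (-1.67). The median was -0.96 with slide as a block and -0.47 within slide 2. The cytokine list was called lower (1 of 41 higher and 1 lower over all probes, 1 and 4 adjusted over the list alone, median -0.14, adjusted p = 0.0271, or adjusted p = 0.779 with an estimated correlation), with IL6 up and IL15 down (-1.43). With slide as a block its median was 0.01 (adjusted p = 0.0704), and within slide 2 it was 0.17. Without day 18 replicate 1 this call ended (adjusted p = 0.312).

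Histotroph genes rose (6 of 27 called over all probes, 11 adjusted over the list alone, median 1.03, adjusted p = 0.0207, or adjusted p = 0.478 with an estimated correlation), among them the secreted inhibitor WFDC2 (3.78), IGFBP3 (3.43), the lectin LGALS3 (1.83) and TIMP1 (1.14). The median was 1.05 with slide as a block and 1.34 within slide 2. Extracellular matrix and remodelling genes rose (4 of 20 called over all probes, 4 adjusted over the list alone, median 0.91, adjusted p = 0.0411, or adjusted p = 0.779 with an estimated correlation), namely SERPINE2 (2.67), TIMP1, the collagenase MMP1 (3.41, above background on 1 of 3 arrays on day 18) and heparanase HPSE (above background on 0 of 3 arrays on day 18). The median was 0.93 with slide as a block and 0.99 within slide 2. Epithelial markers rose (2 of 8 called over all probes, 7 adjusted over the list alone, median 1.27, adjusted p = 0.0114, or adjusted p = 0.646 with an estimated correlation), namely CDH1 (1.76) and CDS1 (1.39), and MAL2 had 1.66. The median was 1.42 with slide as a block and 1.59 within slide 2. The matrix call ended without day 18 replicate 3 and day 24 replicate 1 (adjusted p = 0.243 and 0.108), and the epithelium call without day 18 replicate 2 (0.106). Markers of conceptus and trophoblast, itself an epithelium, had a median of 1.12 over the same days (5 of 20 called higher over all probes, 6 higher and 1 lower adjusted over the list alone, list not called, adjusted p = 0.0664), with AFP at 5.62 (above background on 2 of 3 arrays on day 18) and GATA3 at 2.48. Smooth muscle markers had a median of -1.82 (not called, adjusted p = 0.0523), of -3.53 with slide as a block (adjusted p = 0.000432) and of -3.60 within slide 2.

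Limma called 1691 probes, 1157 higher and 534 lower, with 218 named genes, and 392 with slide as a block; within slide 2, 100% of them and 85.4% of all probes went the same way. Normexp called 207, 166 higher and 41 lower, and the block of libraries sharing on-off probes 520. The count was 1069 without day 18 replicate 3, 261 without day 24 replicate 2 and 309 without day 24 replicate 3.

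**Figure D3:**
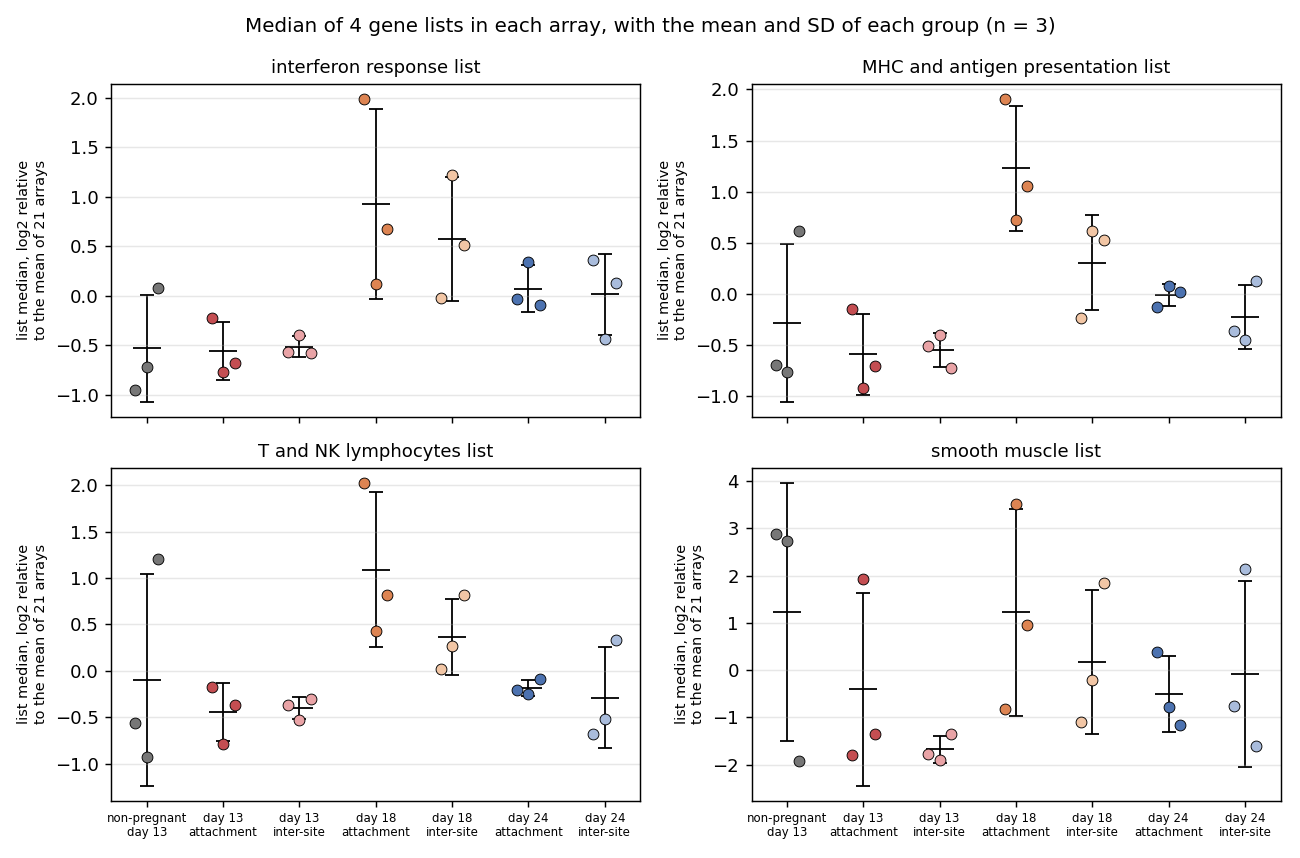
Median of the interferon response, antigen presentation, T and NK lymphocyte and smooth muscle lists on each array, on a log2 scale relative to the mean of the 21 arrays, with the mean and SD of each group (n = 3). Replicate 1 of the day 18 attachment sites was the highest array in the first 3 lists (1.99, 1.91 and 2.03), and non-pregnant replicate 3 had 1.20 for lymphocytes. The smooth muscle list spread from -1.93 to 2.89 within the non-pregnant group alone.

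At inter-sites, the interferon response list rose from day 13 to day 18 (0 of 25 called over all probes, 4 adjusted over the list alone, median 1.11, adjusted p = 8.48e-16, or adjusted p = 0.478 with an estimated correlation). The antiviral genes ISG15 was at 2.68, RSAD2 at 2.50, DDX58 at 1.90 and USP18 at 1.52. Its median was 1.10 with slide as a block and 0.67 within slide 6. Antigen presentation genes rose (0 of 22 called over all probes, 1 adjusted over the list alone, median 0.82, adjusted p = 2.85e-12, or adjusted p = 0.478 with an estimated correlation). SLA-3 was at 1.69 and PSMB8 at 1.67. The median was 0.87 with slide as a block and 0.21 within slide 6. T and NK lymphocyte markers rose (0 of 14 called, also adjusted over the list alone, median 0.58, adjusted p = 0.00629, or adjusted p = 0.694 with an estimated correlation). CD2 was at 1.39 and CD8A at 1.32. The median was 0.96 with slide as a block and 0.32 within slide 6. Calcium and ion handling genes fell (0 of 21 called, also adjusted over the list alone, median -0.44, adjusted p = 0.00191, or adjusted p = 0.360 with an estimated correlation). The calcium-binding S100G was at -3.51 and S100A12 at -2.14. The median was -0.29 with slide as a block (adjusted p = 0.0812) and -0.36 within slide 6. Smooth muscle markers rose (0 of 7 called, also adjusted over the list alone, median 1.90, adjusted p = 0.0271, or adjusted p = 0.779 with an estimated correlation). DES was at 2.28 and TPM2 at 2.0, but with slide as a block their median was -0.11 (adjusted p = 0.928), and within slide 6 it was 0.56. This call ended without any of the day 13 replicates 1, 2 and 3 (adjusted p = 0.0586, 0.0762 and 0.0568) and without day 18 replicates 2 and 3 (0.0581 and 0.242).

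Limma called 2 probes, both lower: BHMT, at least 3.76-fold lower on day 18, and a probe without a symbol (1648 at an unadjusted p under 0.05). With slide as a block it called 0 (1426), and 0 with the block of libraries sharing on-off probes; without any 1 of the 3 day 13 replicates or day 18 replicates 1 and 2 the count was 0, and without day 18 replicate 3 it was 6. Quantile normalization also called 2, 1 higher and 1 lower. Whether the day 18 rise in interferon genes differed between site types was not shown, as the test of that difference called 0 probes.

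From day 18 to day 24 at inter-sites, PMEPA1, an inhibitor of TGF-beta signalling, rose 3.72-fold (log2 fold change 1.90, SE 0.35, adjusted p = 0.0488, n = 3 per group), PGLYRP2 rose by 1.76 (SE 0.33, adjusted p = 0.0498), and MMP1 was at least 5.43-fold higher on day 24. The interferon response list fell (0 of 25 called, also adjusted over the list alone, median -0.64, adjusted p = 1.61e-06, or adjusted p = 0.688 with an estimated correlation). CXCL10 was at -2.43, GBP1 at -2.08 and OASL at 1.38. The median was -0.55 with slide as a block, and -1.78 and 0.15 within slides 4 and 6. Antigen presentation genes fell (0 of 22 called, also adjusted over the list alone, median -0.66, adjusted p = 1.61e-06, or adjusted p = 0.646 with an estimated correlation). SLA-DRA was at -0.81. The median was -0.66 with slide as a block, and -1.06 and -0.36 within slides. T and NK lymphocyte markers fell (0 of 14 called over all probes, 1 adjusted over the list alone, median -0.77, adjusted p = 5.65e-05, or adjusted p = 0.499 with an estimated correlation). GZMB was at -1.35. The median was -0.69 with slide as a block, and -0.69 and -0.76 within slides.

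Calcium and ion handling genes rose over the same days (0 of 21 called over all probes, 9 adjusted over the list alone, median 0.77, adjusted p = 0.000897, or adjusted p = 0.360 with an estimated correlation). S100G was at 4.66, S100A8 at 3.71, S100A12 at 3.52 and the chloride channel CFTR at 2.56 (above background on 2 of 3 arrays on day 18). The median was 0.89 with slide as a block, and 1.02 and 0.67 within slides 4 and 6. Extracellular matrix genes rose (1 of 20 called over all probes, 4 adjusted over the list alone, median 0.73, adjusted p = 0.00819, or adjusted p = 0.634 with an estimated correlation). MMP1 called and SERPINE2 was at 2.08. The median was 0.62 with slide as a block, and 1.26 and 0.07 within slides. Adhesion molecules and mucins rose (0 of 20 called over all probes, 4 adjusted over the list alone, median 0.55, adjusted p = 0.0410, or adjusted p = 0.634 with an estimated correlation). SPP1 was at 3.09, MUC20 at 3.08 and BSG at 0.86. The median was 0.56 with slide as a block, and 0.93 and 0.62 within slides. The cell cycle list rose (0 of 11 called over all probes, 2 adjusted over the list alone, median 1.87, adjusted p = 0.0179, or adjusted p = 0.779 with an estimated correlation). CDK1 was at 2.73 and PBK at 2.12; with slide as a block its median was 1.40 (adjusted p = 0.0682), and within slides it was 1.83 and 0.39. Day 24 replicates 1, 2 and 3 had list medians of -0.96, 0.25 and 2.36, and without replicate 3 the call ended (adjusted p = 0.330). The adhesion call ended without day 18 replicate 3 and day 24 replicates 1 and 2 (0.0714, 0.117 and 0.0673). The smooth muscle median was -0.31, and 2.13 and 0.24 within slides (not called, adjusted p = 0.317).

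Limma called 43 probes, 29 higher and 14 lower, with 8 named genes, 1 with slide as a block and 9 (6 higher, 3 lower) with the block of libraries sharing on-off probes; within slides 4 and 6, 100% of them and 74.2% and 68.8% of all probes went the same way. The count was 8, 6 and 6 without day 18 replicates 1, 2 and 3, 25, 11 and 70 without day 24 replicates 1, 2 and 3, and 96 without both low-DKK1 libraries; normexp called 6, 5 higher and 1 lower. In each of the 42 called lists the median, the mean and the test had the same sign, and 18 of these lists were also called by fry.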

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

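The tests of the patterns weighed below were chosen after the results were seen, whereas the counts over other splits of the arrays were chosen before the data were examined.

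The difference between attachment site and inter-site changed from day 18 to day 24 for 3 probes by the test of that change, all with a larger site difference on day 24. For CYP19A3, the pig aromatase, the fitted change was 5.43 (SE 0.75, adjusted p = 0.0233), which is no measured fold, since the probe was above background on 3 of 3 arrays of day 24 attachment sites and on 0 arrays of the day 18 groups and the day 24 inter-sites. The unnamed probe A_72_P334833 had a fitted change of 4.97 (SE 0.67, adjusted p = 0.0233), likewise resting on values near background: it was above background on 3 of 3 arrays of day 24 attachment sites and on 0, 1 and 1 of 3 arrays of day 18 attachment sites, day 18 inter-sites and day 24 inter-sites. For IL6 the change was 3.86 (SE 0.56, adjusted p = 0.0314), from a site effect of 0.45 on day 18 to 4.30 on day 24; it was above background on 2 of 3 arrays in both day 18 groups, so the first effect rests on values near background. These probes were chosen after their values were seen. With groups of 3, no test for a single deviating array was made. Without 1 array the number of such probes was 5 (day 18 attachment-site replicate 1), 1 (day 18 inter-site replicate 1), 7 (day 24 attachment-site replicate 1) or 18 (day 24 inter-site replicate 2), and 0 without day 18 attachment-site replicate 3, day 18 inter-site replicate 2 or 3, day 24 attachment-site replicate 3 or day 24 inter-site replicate 3.

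Replicate 3 of the day 24 inter-sites resembled non-pregnant replicate 3 (correlation 0.988 across probes, which are not independent replicates), with DKK1 at -6.13 against 3.54 to 5.68 on 16 arrays of pregnant sows. A shared slide is argued against for this pair, since non-pregnant replicate 3 lay on slide 3 and day 24 inter-site replicate 3 on slide 2. At 45 on-off probes, whose signal is either high or low in a library, 0 of 21 libraries had their best match on their own slide. That count cannot decide the question, since an on-off probe needed at least 5 arrays in each state, more than any slide held. A wrong label, or tissue of a shared animal, remains open: the pair had the same state at 93.3% of the on-off probes, against 37.8% between that non-pregnant library and each other library of its group, though replicates of 1 group reached 93.3% as well (day 13 attachment sites 1 and 2). Per the labels the pair came from different sows, so a shared animal would itself mean a wrong label. Non-pregnant replicate 3 correlated at 0.939 or less with the other day 24 inter-site libraries, replicates 1 and 2. These correlations were not under the lowest pair within the other groups (0.934). The test of a day 24 tissue state resembling the non-pregnant uterus therefore stayed undecided. At on-off probes replicates 1 and 2 matched non-pregnant replicate 3 at 48.9% and 51.1%, so they did not share the likeness. Such a state in replicate 3 alone cannot be told apart from a wrong label. Replicate 1 of the day 13 inter-sites correlated with non-pregnant replicate 3 at 0.968 (0.943 and 0.934 with its own group).

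Conceptus and trophoblast transcripts were higher at attachment sites on day 24 as a list (adjusted p = 0.000112, or adjusted p = 0.483 with an estimated correlation), while 0 of 20 members were called: HBE1 had 7.81 ± 1.18 against 0.58 ± 3.45 (SD, n = 3, adjusted p = 0.0638) and PAG6 7.47 ± 1.02 against 1.0 ± 5.47 (adjusted p = 0.326). The aromatase measured in the list was CYP19A1 (0.05, not called). CYP19A3, another name written for that member, did not enter the list and was called (at least 8.37-fold higher). A slide effect is argued against only weakly. The list's median was 0.68 within slide 4 and 1.33 within slide 2, each from 1 array per group. The inter-site array on slide 2 was replicate 3, which resembled a non-pregnant library. RNA from conceptus tissue in the pieces remains open: of 19 members above background on all day 24 attachment-site arrays, 16 (84.2%) had a higher mean there. This share restates the pattern among members picked for signal in that same group, so it cannot decide the question. Expression by the endometrium itself also remains open, since RNA of mixed tissue does not tell the source. Of 9 members higher by over 1 log2 unit, 2 were above background on all non-pregnant arrays and 3 on none. The 2 were HBE1 and GATA3, with means of -3.13 and 0.20 there against 7.81 and 3.85 at day 24 attachment sites. Signal at the lower levels does not show that the endometrium made the day 24 RNA.

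Smooth muscle transcripts varied between libraries of 1 group, with a range within a group of 0.56 to 4.81 log2 units (the widest in the non-pregnant group, 4.34 in the next) against 2.91 between group means. A slide effect is argued against, since the arrays differed by over 2 log2 units on 4 of the 5 slides that held more than 1. The amount of muscle layer in the pieces remains open: 7 of 7 members (100%) followed the median of the others, the lowest at a correlation of 0.941. No biological explanation was tested, since the design names no difference between libraries of 1 group.

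For the 9 comparisons of 3 with 3 arrays there are 10 splits, too few for a share under 0.05. The real and the highest other count were 536 and 0 for pregnancy at attachment sites, 136 and 1 for pregnancy at inter-sites, 84 and 6 for site on day 24, 541 and 0 then 1691 and 0 for the steps between days at attachment sites, and 2 and 0 then 43 and 2 at inter-sites, each real count reached by 1 split. For site on days 13 and 18 the real count was 0, reached by 10 of 10 splits, and the highest others were 54 and 1432. The split with 1432 set attachment-site replicates 1 and 2 and inter-site replicate 2 against the rest, and such a count, like the 859 and 829 below, points to a structure of the samples. Those libraries lay in 1 set sharing on-off probes, as did inter-site replicate 1 on the other side of the split. Splits of the tests of a change in the site difference did not exclude chance: 100 of 100 reached the real count of 0 between days 13 and 18 (highest other 859), and 6 of 100 the real count of 3 between days 18 and 24 (highest other 829). For the 98 probes shared by the pregnancy comparisons 1 of 100 splits was as large, with 16 the highest other. These splits treat the arrays as independent, although some libraries shared on-off probes and both comparisons shared the controls. They therefore cannot exclude a structure of the samples. With libraries sharing on-off probes as a random block, limma called 0 probes in both comparisons, which leaves none to share. For the 42 called lists chance was not excluded, with 33 of 100 as large and 58 the highest other. Taken singly, 10 of the 42 lists had a p as small in under 5 of 100 relabellings. At attachment sites the interferon response had 6 of 100 for its rise and 12 for its fall. Antigen presentation had 4 and 7 there, and T and NK lymphocytes 13 and 5. Antigen presentation for site on day 18 had 13.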

How the results depend on the processing

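Tests chosen after seeing the data were normexp on the median signal, slide as a random block, sets of libraries with shared on-off probes as a random block, slide as a block for lists and named genes, and the fits without pairs of libraries. Where a count given below moved by over 1.5 times, or a direction turned, the cause was not tested. Counts not given here stayed within 1.5 times under that setting. The signal over background was 2.34 to 3.88 at the median of an array, so that levels near background are uncertain, and a bound is given for genes named by size where a group had no array above it.

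Quantile normalization and the authors' table each called 90 probes for pregnancy at inter-sites, 1 for site on day 18 and 26 for day 24 over day 18 at inter-sites. Subtraction of the array median called 261 for pregnancy at inter-sites. Other scalings moved the median of all probes by at most 0.0663, except for site on day 13 (0.107) and the change of the site difference between days 13 and 18 (0.122), and with normexp that last median was 0.332. Normexp called 26 and 0 probes for pregnancy at attachment sites and inter-sites, 47 for site on day 24, 111 and 207 for the first and the later step between days at attachment sites, 0 and 6 at inter-sites, and 0 for the change of the site difference after day 18. For day 24 over day 18 at attachment sites, the log2 fold change of GZMA was 0.0206 and that of SNCAIP 0.45 with normexp, opposite in direction to the reported falls.

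Without a filter, limma called 182 and 7 probes for pregnancy at attachment sites and inter-sites with 7 shared, 50 for site on day 24, 205 for day 18 over day 13 at attachment sites and 7 for day 24 over day 18 at inter-sites. A filter on all 21 arrays gave 275 for pregnancy at inter-sites, 33 for site on day 24, 0 and 15 for the steps at inter-sites and 0 for the change of the site difference after day 18. With genes in place of probes, fewer tests by construction, the counts were 97 and 65 for pregnancy, 35 for site on day 24, 109 and 232 at attachment sites, 1 for day 18 over day 13 at inter-sites and 1 for the change of the site difference after day 18. Trend and robust settings gave 367 for pregnancy at inter-sites, 0 and 80 for the steps at inter-sites and 0 for that change.

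Array weights raised most counts, to 8111 and 4334 for pregnancy, 1, 1 and 312 for site on days 13, 18 and 24, 2109 and 4066 at attachment sites, 286 and 943 at inter-sites and 9 for the change of the site difference after day 18. A fit of only the groups compared, with fewer samples for the spread, called 1295 and 1 for pregnancy, 0 for site on day 24, 3 and 486 at attachment sites, 0 and 1 at inter-sites and 0 for that change. An added 2-fold threshold kept each count within 1.5 times.

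Slide as a block called 0 and 0 for pregnancy, 22 for site on day 24, 12 and 392 at attachment sites, 0 and 1 at inter-sites and 0 for the change of the site difference after day 18. It turned the direction of the cell cycle list for site on day 18 (adjusted p = 0.482) and of the smooth muscle list for day 18 over day 13 at inter-sites (adjusted p = 0.928). Slide as a random block, with an estimated correlation of -0.056 within slides, gave 25 for day 24 over day 18 at inter-sites. Sets of libraries with shared on-off probes as a random block gave 0 and 0 for pregnancy, 2 and 245 for site on days 18 and 24, 24 and 520 at attachment sites, 0 and 9 at inter-sites and 7 for the change of the site difference after day 18.

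The replicate numbers were not taken to pair the samples, because 4 of 9 rather than all same-number pairs correlated above 0.1; 5 of 9 correlated best with their own number, and 6 of 9 lay in 1 set of libraries with shared on-off probes. Which libraries share a sow is not settled by these values. With a random replicate block the counts were 1, 1 and 206 for site on days 13, 18 and 24, and with a fixed replicate block 52 for site on day 24 and 0 for the change of the site difference after day 18.

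Without day 13 inter-site replicate 1 and day 24 inter-site replicate 3, limma called 1972 and 1162 for pregnancy, 18 for site on day 24, 954 for day 18 over day 13 at attachment sites, 0 and 96 at inter-sites and 0 for the change of the site difference after day 18. Leaving out non-pregnant replicate 3 and day 24 inter-site replicate 3 gave 905 and 516, 23, 930, 5 and 115, and 0 for the same results. Leaving out 1 library at a time, the counts ranged from 0 to 657 for pregnancy at attachment sites, 0 to 612 at inter-sites, 0 to 480 for their overlap, 0 to 3 for site on day 18, 12 to 309 on day 24, 9 to 3728 and 261 to 1618 for the steps at attachment sites, 0 to 6 and 6 to 70 at inter-sites, and 0 to 1 and 0 to 18 for the changes of the site difference; for site on day 13 the count stayed 0 (limma, 2441 at an unadjusted p under 0.05 with all arrays). The highest count was without non-pregnant replicate 3 for pregnancy at attachment sites, and without day 24 replicate 1 for day 24 over day 18 at attachment sites.

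Of 42 called lists, 0 passed with an estimated correlation and 18 by fry, which called 26 of all 189 tests. The other settings called 38 (quantile), 46 (normexp), 48 (no filter), 41 (replicate block) and 47 (slide as a block), and 35 to 53 without 1 library. Of 139 results for named genes, 115 stayed past the threshold with quantile normalization and with the authors' table, 55 with normexp, 133 with the replicate block and 26 with slide as a block.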

Other observations

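The genes of this paragraph were picked after their values were seen, and the written list of steroid genes passed in 0 comparisons. From day 18 to day 24 at attachment sites STAR, which brings cholesterol into mitochondria, rose by 2.97 (SE 0.78, adjusted p = 0.0341, n = 3 per group), HSD17B1 by 2.92 (adjusted p = 0.0146), HSD3B1 by 2.34 (adjusted p = 0.0116), CYP11A1 by 2.12 (adjusted p = 0.00725) and HSD11B2 by 2.01 (adjusted p = 0.0407). HSD17B1 was also higher at attachment sites than at inter-sites on day 24, by 3.05 (adjusted p = 0.0478). RNA from conceptus tissue in the pieces was not excluded as a source of these transcripts. The scavenger receptor CD163 of macrophages rose over the same days by 2.48 (adjusted p = 0.0160) and the fatty acid carrier FABP3 by 2.70 (adjusted p = 0.0370). PROX1, a factor of lymphatic endothelium, fell by 2.11 (adjusted p = 0.0468). CD163 levels at attachment sites were 3.2, 2.0 and 1.8 on day 13 and -0.3, 1.0 and 0.2 on day 18. The macrophage and myeloid list did not rise with CD163: its medians were 1.3, 0.5 and 0.6 on day 18 and 0.3, 0.4 and 0.4 on day 24.

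Levels of genes often studied in the pig uterus, also chosen after the values were seen, follow as mean ± SD of 3 arrays. The oestrogen receptor ESR1 had 2.21 ± 0.43 in non-pregnant sows and 0.67 ± 0.25 at day 13 attachment sites (adjusted p = 0.0602). STC1 had -5.12 ± 1.40 and 1.14 ± 2.05 in the same groups (adjusted p = 0.0560), with 1 of the 3 non-pregnant arrays above background. PTGS2, which starts prostaglandin synthesis, had -0.58 ± 0.45 and 1.90 ± 1.04 (adjusted p = 0.172). The lysophosphatidic acid receptor LPAR3 lay near background, at -4.32 ± 1.05 and -4.39 ± 1.09. Uteroferrin ACP5 had 8.18 ± 1.85 and 9.04 ± 0.08, and RBP4 5.42 ± 1.01 and 8.34 ± 0.08 (adjusted p = 0.191). On replicate 3 of the day 24 inter-sites ACP5 was 6.35, RBP4 5.33 and ESR1 1.90, and on replicate 1 of the day 13 inter-sites RBP4 was 1.98 and ESR1 2.04.

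Lists that passed in 0 of the 9 comparisons had these lowest adjusted p values: macrophages and other myeloid cells 0.0534 (site on day 18, median 0.69), steroid receptors and metabolism 0.0664 (site on day 18, median -0.08), immediate early and heat shock genes 0.0948 (day 18 over day 13 at inter-sites, median 0.30), nutrient transporters 0.170 (site on day 18, median 0.12 but mean -0.09) and endothelium 0.185 (day 24 over day 18 at inter-sites, median -0.25). Over the 9 comparisons 5, 8, 4, 3 and 1 of their members were called, and 19, 25, 4, 13 and 2 adjusted over the list alone. Markers of ciliated epithelium (1 measured), stromal fibroblasts (3), blood cells and platelets (4) and B and plasma cells (0) had too few measured members for a test.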
